A study of Sus scrofa with 80 samples.

How the data were processed

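Expression in the blood of pigs at day 35 was measured on 80 Affymetrix porcine arrays, in 8 trait pairs with 5 arrays in the low and 5 in the high self-product group. Per the labels, the authors processed the arrays with RMA and used limma, without versions or settings. The deposited values are log2 expression per probe set. Means of whole arrays were almost equal within a pair (range at most 0.0642) and differed between pairs (5.66 to 6.08), so each pair had been normalized as a set of its own. The deposited table holds 24123 probe sets; 124 control probe sets were set aside and 23999 were tested. By the platform's annotation, 10069 of these carry 1 gene symbol, 198 several and 13732 none, and 6765 genes were left with 1 probe set per gene, the one with the highest mean over the distinct arrays. Genomic positions and the genome build were not used here. An array gives no count, so its depth is unknown and the number of arrays limits the precision.

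Arrays with a correlation above 0.99 were taken as the same pig, with values normalized again in another pair. Because the same pigs recur, each pair was tested on its own 10 arrays. R 4.3.3 was used with limma 3.58.1 and, for reading files, data.table (version 1.17.8). A linear model with 1 group term was fitted to each probe set, moderated with eBayes at default settings, and adjusted with the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. Counts at an unadjusted p under 0.05 are set beside the 5% that chance gives. All tests were two-sided. Replicate numbers were not taken as a pairing: after removing group means, arrays with the same number correlated between -0.544 and 0.365. No pair of groups had all 5 correlations over 0.1, but 4 of 5 were over it in CD4+ with W35 and 3 in CD8+ with IL-10. In CD4+ with W35, 3 of 5 arrays correlated best with their own number.

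Before the data were examined, 30 gene lists for blood cell types, immune signals, growth and cell functions were fixed, as were the tests and most alternatives. Of these, 25 lists had at least 5 genes on the array and were tested with camera (preset correlation 0.01) on 1 probe set per gene, adjusted over the lists of a pair. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were alternatives. An exact permutation test of each list's mean per array over all 252 assignments was added after seeing the data. The rule for named genes was also fixed: since no probe set passed, it takes, among probe sets with 1 symbol and a mean at or above the median, up to 8 genes per direction with the smallest p whose high and low arrays do not overlap. It adds the genes of the traits themselves and up to 4 members of each called list. Where a further list member is named, it was chosen after its values were seen.

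Alternatives changed 1 choice at a time: quantile normalization again, centring on the array median, a filter at the median probe set, eBayes with trend and robust settings, array weights, erythroid and neutrophil list means as covariates, the replicate number as a replicate block, 1 probe set per gene, an adjusted p under 0.1, an unadjusted p under 0.01 with a 1.5-fold change, the mean of a gene's probe sets, and leaving out each array. Added after seeing the data were the spike-in class as a block, the higher spike-in class alone, and covariates for EIF1AY and for the difference of the 3′ and 5′ actin controls. For the number of genes and lists, 100 of the 126 splits of each pair's 10 arrays into 5 and 5 were drawn, the real one included. The agreement of pairs was set beside 100 permutations of pig profiles over the pigs. A permutation test of list means between EIF1AY classes used 100000 resamples.

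The scripts were tested on simulated data with the spread of each pair: of 100 probe sets with a 2-fold change 38 to 69 were recovered, and of 100 with a 4-fold change 79 to 100, with 5 to 11 false calls. A list shifted by 0.5 was called in 8 of 8 pairs, with 1 other list called beside it in 1 pair and 0 in the other 7. In data simulated with no effect at all, 0 lists were called. Genes were simulated without correlation between them, so this does not show how often camera calls lists by chance in the real arrays. There, the splits other than the real one called a median of 5 (CD4+ with W35) to 8 (CD8+ with IL-10) lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The deposited sheet of group labels by array holds no measurement; only the numbers that its groups have in common were counted, after seeing the data, to check which arrays are of the same pig.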

Results

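Blood taken from pigs at day 35 was measured on a porcine expression array. The 80 arrays form 8 trait pairs, and each pair joins 2 traits of the same animal. The traits were the T cell markers CD4+ and CD8+, the cytokines IFN-alpha and IL-10, and body weight at day 35, labelled W35. Each pair holds 5 arrays labelled low and 5 labelled high for the self-product of its traits, by its name a product of the 2 trait values; its formula is not used here. The values are log2 expression per probe set, between 2.15 and 14.96, with array medians from 5.17 to 5.80. All differences below are high minus low, with SD given for group means, SE from limma for genes and SE of a difference of means for gene lists. Each group has n = 5, and the number of arrays limits the precision.

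The same pig served in several pairs. Arrays were taken as the same pig at a correlation above 0.99, which left 29 pigs among the 80 arrays. The highest correlation between different pigs was 0.9883 and the lowest within 1 pig was 0.9935. The deposited sheet of labels also held 29 distinct array numbers, with as many in common as by correlation in 120 of 120 combinations of 2 groups. Of these, 21 were in 2 or more pairs, and 13 were labelled high in some pairs and low in others. Hybridisation controls split the arrays on something other than the groups: bioB minus bioC was at most -2.73 in 26 arrays from 11 pigs (the lower spike-in class) and at least -1.82 in 54 arrays from 18 pigs (the higher class). EIF1AY, a gene on the Y chromosome, was at most 3.50 in 18 pigs and at least 6.98 in 11.

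The question in each pair was which genes differ in blood between pigs with a low and a high self-product. No probe set passed an adjusted p of 0.05 in limma in any of the 8 pairs, while 474 to 2143 of 23999 had an unadjusted p under 0.05, against 1200 expected by chance. The direction that held more of these was the other one in 1 to 8 of 22 settings, depending on the pair, so the numbers of higher and lower probe sets below depended on the setting. Individual genes are therefore given as values and not as changes. Gene lists fixed before the data were examined were tested with camera, which compares a list with all other genes. Every call of camera was made with its preset correlation. With an estimated correlation or with fry, no list was called in any pair. An exact permutation test of list means also called none, but this decides little. Its smallest possible p was 0.00794, so several lists of a pair would have to separate completely or nearly so before any passed after adjustment. Of 100 splits of the same arrays drawn per pair, at least 14 gave as many called lists as the real groups, so chance was not excluded for the number of lists in any pair. List means without 1 array are given below where the call ended or the mean moved by over 1.5 times, and had SE of 0.0542 to 0.546.

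**Figure D1:**
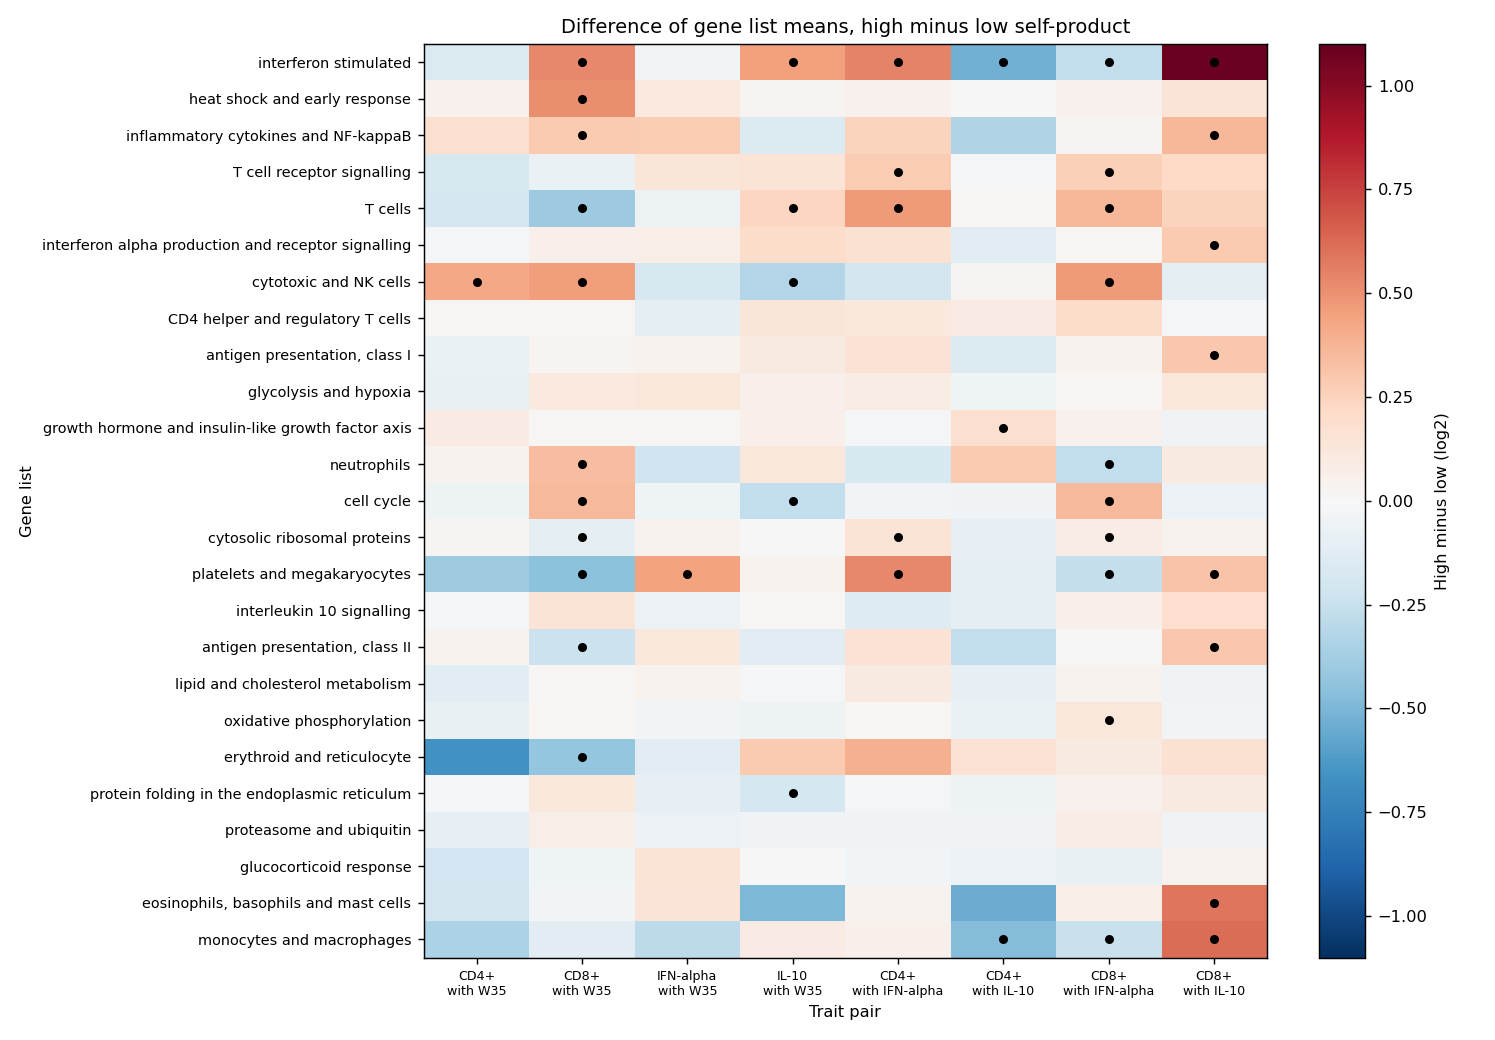
Difference of the mean of each of 25 gene lists (vertical) between the high and low self-product groups in each of 8 trait pairs (horizontal), in log2 units by colour, with 5 arrays per group. Black points mark lists with an adjusted p under 0.05 in camera with the preset correlation; the highest difference is 1.09, for interferon-stimulated genes in CD8+ with IL-10.

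In the CD4+ and W35 pair, genes of cytotoxic lymphocytes were higher in the high group. CCL5, a chemokine of activated T and NK cells, measured 10.86 ± 0.23 in the low group and 12.19 ± 0.27 in the high group (SD, n = 5 each), a difference of 1.33 (SE 0.17). GZMH, a granzyme, was higher by 1.32 (SE 0.25), and GNLY, the granule protein granulysin, by 1.02 (SE 0.26). KLRK1, an activating receptor of NK and CD8 T cells, was higher by 0.90 (SE 0.27) and CTSW, a cathepsin of cytotoxic cells, by 0.42 (SE 0.14). These were 5 of the 12 measured genes of the cytotoxic and NK cell list, and all 5 passed when p was adjusted over the list alone; 8 of the 12 were higher and none passed over all probe sets. The list mean differed by 0.43 (SE 0.14, median gene 0.19), and it lay above all low arrays in 3 of 5 high arrays. Its adjusted p was 3.44e-04 in camera, and adjusted p = 0.638 with an estimated correlation. Within the higher spike-in class (3 low and 4 high arrays) the list mean differed by 0.28, while the lower class held 2 low arrays and 1 high array, too few for a value. The mean of the erythroid list was 8.76 ± 0.72 in the low group and 8.10 ± 0.51 in the high group.

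Other genes whose 5 high and 5 low arrays did not overlap in this pair included THBS2, a matrix thrombospondin, higher by 0.93 (SE 0.23). KLK7, a serine protease of the kallikrein family, differed by -1.24 (SE 0.22), PPP1R12A, a subunit of myosin phosphatase, by -1.15 (SE 0.24) and ST6GAL1, a sialyltransferase, by -0.92 (SE 0.23). TPP2, a cytosolic peptidase, differed by -0.92 (SE 0.17). EEF1A1, ZC3H11A, MAP4K4, ABCC6 and NDUFB7 were higher by 0.55 to 0.95, and MAN1C1, DCAF12, VPS45 and NREP were lower, between -1.19 and -0.79. The adjusted p was 0.159 for CCL5 and 0.552 for the other 15 genes. CD4 itself was near the bottom of the scale at 3.98 ± 0.30 and 4.09 ± 0.33. GHR, the growth hormone receptor, differed by 0.29 (SE 0.13, p adjusted over the trait genes alone 0.217). With limma, the adjusted threshold was passed by 0 probe sets and 2143 had an unadjusted p under 0.05, 990 higher and 1153 lower. With erythroid and neutrophil means as covariates the total of 2143 became 944, 375 higher and 569 lower. High replicate 1 had the lowest median correlation in the pair (0.926), and without it 928 were higher and 703 lower. The median filter gave 380 and 883, and more were higher than lower in 4 of 22 settings. The adjusted threshold was passed by 6 probe sets without low replicate 2 and by 2 without high replicate 4, CCL5 among both. Groups did not overlap for 394 probe sets, 1.64% where chance gives 0.794%.

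The CD8+ and W35 pair had more lists called, 6 higher and 5 lower. Cell cycle genes were higher in 20 of 22 cases: RRM2, a subunit of ribonucleotide reductase, measured 8.21 ± 0.54 and 9.63 ± 0.39, a difference of 1.42 (SE 0.27). BIRC5, the mitotic protein survivin, differed by 0.56 (SE 0.14) and CCNB2, a mitotic cyclin, by 0.68 (SE 0.18); these 3 passed when adjusted over the list alone. The list mean differed by 0.35 (SE 0.12), with adjusted p = 3.00e-08 in camera and adjusted p = 0.205 with an estimated correlation. CCL5 was again higher, by 1.22 (SE 0.26), and KLRK1 by 1.14 (SE 0.33), both passing over the list alone; 10 of 12 cytotoxic and NK cell genes were higher (adjusted p = 1.78e-04, and adjusted p = 0.205 with an estimated correlation). In the higher spike-in class (2 low and 3 high arrays) the cell cycle and cytotoxic means differed by 0.24 and 0.18, and in the lower class (3 low and 2 high) by 0.46 and 0.76. Genes of the early stress response were higher in 18 of 20 cases, among them the immediate early genes JUN by 1.22 (SE 0.44) and IER3 by 1.10 (SE 0.35), none passing over the list alone (adjusted p = 5.72e-06, and adjusted p = 0.205 with an estimated correlation). Interferon-stimulated genes were higher in 22 of 23 cases with GBP2 and GBP1, interferon-induced GTPases, at 1.21 (SE 0.39) and 1.02 (SE 0.34); none passed over the list alone (adjusted p = 1.53e-06, and adjusted p = 0.579 with an estimated correlation). The means of that list differed by 0.10 in the higher spike-in class and 0.87 in the lower.

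Genes of T cells were lower in this pair in 10 of 11 cases. LEF1, a transcription factor of naive T cells, measured 9.68 ± 0.70 and 8.38 ± 0.57, a difference of -1.30 (SE 0.36) that passed over the list alone; CCR7, a homing receptor of naive T cells, differed by -0.55 (SE 0.21). The T cell list had adjusted p = 5.54e-04 in camera, and adjusted p = 0.414 with an estimated correlation. Platelet genes were lower in 9 of 10 cases, with PPBP, a platelet chemokine, at -0.83 (SE 0.35) (adjusted p = 1.52e-03, and adjusted p = 0.358 with an estimated correlation). Ribosomal protein genes were lower in 56 of 59 cases by a mean of only -0.10 (SE 0.09) (adjusted p = 1.02e-04, and adjusted p = 0.734 with an estimated correlation). Erythroid genes were lower in 13 of 16 cases, with FECH, the last enzyme of haem synthesis, at -1.12 (SE 0.44) (adjusted p = 7.61e-03, and adjusted p = 0.66 with an estimated correlation). Class II antigen presentation genes were lower in 11 of 14 cases, with SLA-DMA at -0.53 (SE 0.25) (adjusted p = 7.07e-03, and adjusted p = 0.686 with an estimated correlation). Neutrophil genes were higher in 12 of 13 cases, with LTF, lactoferrin, at 1.14 (SE 0.54) (adjusted p = 0.0233, and adjusted p = 0.686 with an estimated correlation). Inflammatory cytokine genes were higher in 14 of 19 cases, with TNF at 1.25 (SE 0.50) and CCL4, a chemokine, at 1.0 (SE 0.35) (adjusted p = 0.0243, and adjusted p = 0.716 with an estimated correlation). Without high replicate 4 the calls of the T cell, erythroid, class II, ribosomal, neutrophil and inflammatory lists ended, at adjusted p of 0.0657, 0.152, 0.446, 0.116, 0.116 and 0.262. Without high replicate 3 the neutrophil (0.699), inflammatory (0.48) and erythroid (0.0773) calls ended, and without low replicate 1 the class II, erythroid and neutrophil (0.0533 each) and inflammatory (0.0797) calls. The inflammatory call also ended without high replicate 2 (0.0848) and the erythroid call without low replicate 5 (0.0891). With the 3′ and 5′ actin difference, a measure of RNA quality, as a covariate the class II and inflammatory calls ended (0.0722 each) at means of -0.14 (SE 0.22) and 0.29 (SE 0.35), against -0.23 (SE 0.24) and 0.29 (SE 0.32) without it.

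The list means of this pair depended on single arrays. Over all arrays the T cell, erythroid and neutrophil means differed by -0.40 (SE 0.21), -0.43 (SE 0.37) and 0.34 (SE 0.28). Without high replicate 4 the T cell, erythroid, class II, ribosomal, neutrophil and inflammatory means differed by -0.259, -0.276, -0.0552, -0.0364, 0.248 and 0.133. Without high replicate 3 the neutrophil, inflammatory and erythroid means differed by 0.115, 0.128 and -0.243. Leaving out low replicate 1 gave -0.278 for the erythroid and -0.171 for the class II list, but 0.373 for neutrophils and 0.307 for inflammatory genes, neither of them smaller than with all arrays. The inflammatory mean was 0.246 without high replicate 2, and the erythroid mean was -0.321 without low replicate 5. Some means moved while the call held. The interferon-stimulated mean was 0.348 without low replicate 3, 0.345 without high replicate 3 and 0.796 without high replicate 5, against 0.53 (SE 0.36). Inflammatory genes gave 0.457 without high replicate 1 and 0.481 without high replicate 5, and ribosomal proteins -0.155 without the latter.

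Further genes without overlap in the CD8+ and W35 pair were S100A1, a calcium-binding protein, at 1.28 (SE 0.26) and the mitotic kinase MELK at 0.66 (SE 0.15). RHOB, CLK1 and APITD1 were higher by 0.73 to 1.02. ID3, an inhibitor of DNA binding, differed by -0.60 (SE 0.12), CTSC, a cathepsin that activates granzymes, by -0.94 (SE 0.24), and DAPL1 by -1.24 (SE 0.33). MAT2A, PADI2, SENP5, NPC2 and ARFGEF2 were lower, between -0.84 and -0.30. CD8A, which encodes a chain of the CD8 molecule, measured 8.67 ± 0.47 and 9.54 ± 0.78, a difference of 0.88 (SE 0.36, p adjusted over the trait genes alone 0.197), and CD8B differed by 0.49 (SE 0.34). At the adjusted threshold limma gave 0 probe sets, and 822 had an unadjusted p under 0.05, 425 higher and 397 lower; centred on the array median these were 541 and 291, and in the higher spike-in class alone 267 and 681. High and low arrays did not overlap for 98 probe sets, 0.408% against 0.794% by chance.

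In the IFN-alpha and W35 pair, all 10 platelet and megakaryocyte genes were higher in the high group. RGS18, a signalling regulator abundant in platelets, measured 9.64 ± 0.62 and 10.77 ± 0.42, a difference of 1.13 (SE 0.29), the only gene to pass when adjusted over the list alone. PPBP was higher by 0.66 (SE 0.25) and ITGB3, a subunit of the platelet fibrinogen receptor, by 0.74 (SE 0.33). The list had adjusted p = 1.31e-03 in camera, and adjusted p = 0.981 with an estimated correlation. Its mean differed by 0.44 (SE 0.29), and by 0.33 and 0.76 within the higher (3 low, 2 high) and lower (2 low, 3 high) spike-in classes, while no high array lay above all low arrays. Without low replicate 5 the call ended, at an adjusted p of 0.0956 and a mean of 0.233.

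Genes without overlap in that pair included PTGS1, the cyclooxygenase found in platelets, higher by 1.30 (SE 0.35), and CAMK2N1, an inhibitor of calmodulin kinase II, by 0.95 (SE 0.16). FDPS, an enzyme of the mevalonate pathway, was higher by 0.66 (SE 0.16). UBE2W, COMMD7, APEX1, MGMT and UXS1 were higher by 0.49 to 0.69. RASSF4 differed by -1.31 (SE 0.25), CPT1A, which brings fatty acids into mitochondria, by -1.0 (SE 0.23), and XBP1, a transcription factor of the unfolded protein response, by -0.56 (SE 0.12). FKBP15, SDF2, STX18, MED6 and ATRAID were lower, between -0.71 and -0.34. The adjusted p was 0.999 for all 16. Both chains of the IFN-alpha receptor were lower without passing: IFNAR1 differed by -0.53 (SE 0.26) and IFNAR2 by -0.42 (SE 0.17, p adjusted over the trait genes alone 0.227), although another probe set of IFNAR2 showed almost no difference (0.0167 in log2). IFNA1 measured 6.48 ± 0.16 and 6.44 ± 0.11. In limma 0 probe sets passed the adjusted threshold and 1018 had an unadjusted p under 0.05, 529 higher and 489 lower; 153 probe sets did not overlap between groups, 0.638% against 0.794% by chance.

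In the IL-10 and W35 pair the cell cycle genes lay the other way, lower in 19 of 22 cases in the high group. RRM2 measured 9.63 ± 0.29 and 8.55 ± 0.62, a difference of -1.08 (SE 0.28), and TOP2A, a DNA topoisomerase of dividing cells, differed by -0.71 (SE 0.20); these 2 passed when adjusted over the list alone. The list had adjusted p = 1.41e-06 in camera, and adjusted p = 0.585 with an estimated correlation. Genes for protein folding in the endoplasmic reticulum were lower in 17 of 20 cases, with the chaperone HSPA5 at -0.49 (SE 0.16) and DNAJB9 at -0.60 (SE 0.19) (adjusted p = 1.22e-04, and adjusted p = 0.585 with an estimated correlation). Of 12 cytotoxic and NK cell genes 6 were lower and 6 higher, with CCL5 at -1.03 (SE 0.35), GZMH at -1.01 (SE 0.39) and FCER1G, a signalling chain shared with myeloid cells, at 0.44 (SE 0.19) (adjusted p = 0.0389, and adjusted p = 0.585 with an estimated correlation). Interferon-stimulated genes were higher in 21 of 23 cases, with MX1, an antiviral GTPase, at 0.77 (SE 0.48) (adjusted p = 5.70e-04, and adjusted p = 0.769 with an estimated correlation). T cell genes were higher in 9 of 11 cases, with CD27, a costimulatory receptor, at 0.85 (SE 0.26) (adjusted p = 0.0389, and adjusted p = 0.707 with an estimated correlation). The higher EIF1AY class held 1 low and 4 high pigs here, and with EIF1AY as a covariate the mean of the interferon-stimulated list differed by -0.43 (SE 0.42), against 0.45 (SE 0.49) without it. The lower spike-in class held only low replicate 1, so the class as a block equals leaving that array out. The cell cycle mean then differed by -0.21 and the interferon-stimulated mean by 0.61. The T cell and cytotoxic calls ended (adjusted p of 0.146 and 0.0677) at means of 0.18 (SE 0.19) and -0.31 (SE 0.19), against 0.23 (SE 0.18) and -0.33 (SE 0.17) over all arrays. The T cell call also ended without low replicates 2 (0.065) and 4 (0.283) and high replicates 1 (0.165) and 3 (0.152). The cytotoxic call ended without low replicates 3 (0.0694), 4 (0.187) and 5 (0.0565) and high replicates 3 (0.152) and 5 (0.121). For interferon-stimulated genes this held without low replicates 2 (0.149) and 5 (0.0565), and for protein folding without low replicate 4 (0.0549). With the actin covariate the T cell call ended (0.0644) at 0.21 (SE 0.16). The cytotoxic mean stayed near its value over all arrays without low replicates 3, 4 and 5 and high replicate 5 (-0.313, -0.294, -0.296 and -0.294) and was -0.25 without high replicate 3. The T cell mean was 0.252 and 0.11 without low replicates 2 and 4, and 0.207 and 0.186 without high replicates 1 and 3. The interferon-stimulated mean was 0.263 without low replicate 2, 0.264 without low replicate 5, 0.713 without low replicate 4 and 0.773 without high replicate 5. The protein folding mean was -0.11 without low replicate 4, against -0.20 (SE 0.12), and the cell cycle mean -0.182 without high replicate 5, against -0.275 (SE 0.15). Of the genes named here, EIF1AY as a covariate moved CCL5 to -0.51, FCER1G to 0.18, MX1 to -0.32 and DNAJB9 to -0.31.

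IL10 itself was lower in the high group of the IL-10 and W35 pair: 8.91 ± 0.56 against 7.89 ± 0.45, a difference of -1.02 (SE 0.29). It passed when adjusted over the trait genes alone (0.0253) but not over all probe sets (1.0). It did not pass with the spike-in class as a block, with EIF1AY as a covariate, with renewed quantile normalization, or in 6 of 10 cases of leaving out 1 array (low replicates 1, 3, 4 and 5, high replicates 3 and 4). Its size was close to -1.02 in the first 3 of these settings, -0.996, -1.07 and -1.05, and lay from -1.04 to -0.854 without those arrays. JAML, an adhesion molecule of leukocytes, was higher without overlap by 0.85 (SE 0.16), SPIB, a B lymphoid transcription factor, by 0.71 (SE 0.21; 0.44 with EIF1AY as a covariate) and CDA, cytidine deaminase, by 0.57 (SE 0.15). HNRNPH2, LOC100625971, CSNK1D, SS18L2 and SPPL3 were higher by 0.47 to 0.79. APITD1, a component of the kinetochore, differed by -0.82 (SE 0.16) and PCK2, the mitochondrial PEP carboxykinase, by -0.67 (SE 0.16). SPTY2D1, MTPAP, SMNDC1, ENOSF1 and CWC15 were lower, between -0.81 and -0.61. With limma, the adjusted threshold was passed by 0 probe sets and 766 had an unadjusted p under 0.05, 417 higher and 349 lower; with renewed quantile normalization these were 372 and 444. Groups did not overlap for 128 probe sets, 0.533% against 0.794% by chance.

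In the CD4+ and IFN-alpha pair 5 lists were called, all higher in the high group. Platelet genes were higher in 8 of 10 cases: ITGA2B, the other subunit of the platelet fibrinogen receptor, measured 9.43 ± 0.34 and 10.48 ± 0.49, a difference of 1.05 (SE 0.24) that passed when adjusted over the list alone. Interferon-stimulated genes were higher in 21 of 23 cases, with IFIT3 at 1.14 (SE 0.38) and IFIT1 at 0.90 (SE 0.31), both inhibitors of viral RNA translation. T cell genes were higher in 11 of 11 cases, with the naive T cell genes LEF1 at 0.86 (SE 0.51) and CCR7 at 0.39 (SE 0.15). Genes of T cell receptor signalling were higher in 13 of 15 cases, with DGKA, a diacylglycerol kinase, at 0.75 (SE 0.29), and ribosomal protein genes in 57 of 59 by a mean of 0.15 (SE 0.17). The adjusted p in camera was 1.25e-03, 1.09e-03, 2.01e-03, 0.0106 and 1.09e-03 in that order, and adjusted p = 0.981 with an estimated correlation for all 5. The higher EIF1AY class held 1 low and 5 high pigs; with EIF1AY as a covariate the mean of the interferon-stimulated list differed by -0.95 (SE 0.67), against 0.55 (SE 0.49) without it, and the platelet call ended (adjusted p of 0.27) at a mean of 0.27 (SE 0.54), against 0.53 (SE 0.29). With the same covariate IFIT3 and IFIT1 differed by 0.20 and 0.06, and LEF1 and DGKA by 1.76 and 1.67. All 5 calls ended on leaving out 1 array: ribosomal proteins (0.829) and T cells (0.154) without low replicate 5, and platelets and interferon-stimulated genes (0.11 each) without low replicate 3. Without high replicate 2 the T cell (0.0586), interferon-stimulated and receptor signalling (0.0734 each) calls ended. Low replicate 5 had the lowest median correlation in the pair (0.934) and the highest neutrophil mean (10.17), and is the same pig as high replicate 5 of CD4+ with IL-10 and low replicate 4 of CD8+ with IL-10. Without it the ribosomal mean differed by -0.00754, the T cell mean by 0.143, against 0.47 (SE 0.38), and the receptor signalling mean, still called, by 0.151, against 0.28 (SE 0.18). The platelet and interferon-stimulated means were 0.339 and 0.406 without low replicate 3. Without high replicate 2 the T cell, interferon-stimulated and receptor signalling means stayed at 0.42, 0.443 and 0.271. The interferon-stimulated mean was 0.881 without low replicate 1, 0.363 without high replicate 1 and 0.832 without high replicate 4, where its call held. In the higher spike-in class (3 low, 4 high) the platelet, interferon-stimulated and T cell means differed by 0.75, 0.72 and 0.16, while the lower class held 2 low arrays and 1 high array.

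Genes without overlap in that pair included WNK4, a kinase that regulates salt transport, higher by 1.30 (SE 0.26), and a further probe set of IFIT2 by 1.55 (SE 0.42), or 0.66 with EIF1AY as a covariate. That covariate also moved GSE1 from 0.59 to 0.36, MAN1C1 from 0.65 to 0.38, BRF2 from -0.745 to -0.39 and CWC15 from -0.83 to -0.36. TMEM40 was higher by 1.07 (SE 0.28), and GSE1, GGA2, SIAH2 and MAN1C1 by 0.53 to 0.70. The MAN1C1 probe set here (5.71 and 6.35) is another one than that named as lower in CD4+ with W35 (9.04 and 8.25). AZIN1, an inhibitor of antizyme in polyamine synthesis, differed by -0.88 (SE 0.18) and PLIN2, a coat protein of lipid droplets, by -0.61 (SE 0.14). BRF2, CWC15, CCZ1, TAS1R3, ALDH3A2 and TMEM185B were lower, between -0.83 and -0.30. The adjusted p was 0.971 for all 16. CD4, IFNA1, IFNAR1 and IFNAR2 differed by 0.15, -0.19, 0.19 and 0.28, all with p adjusted over the trait genes alone of 0.487. At the adjusted threshold limma gave 0 probe sets and 929 had an unadjusted p under 0.05, 493 higher and 436 lower. These became 416 and 513 with renewed quantile normalization and 336 and 120 with the median filter. With EIF1AY as a covariate 4 probe sets passed, and 7 passed without low replicate 1. That array (EIF1AY 7.52) is the only low array of the higher EIF1AY class. Without it the groups coincide with the EIF1AY classes, so the 7 cannot be told apart from a difference between those classes. High and low arrays did not overlap for 121 probe sets, 0.504% against 0.794% by chance.

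In the CD4+ and IL-10 pair monocyte genes were lower in the high group in 13 of 15 cases. KLF4, a transcription factor of monocyte differentiation, measured 8.63 ± 0.39 and 7.07 ± 0.51, a difference of -1.56 (SE 0.26), and AIF1, a calcium-binding protein of macrophages, differed by -0.87 (SE 0.26); these 2 passed when adjusted over the list alone. The list had adjusted p = 1.09e-03 in camera, and adjusted p = 0.775 with an estimated correlation. Interferon-stimulated genes were lower in 20 of 23 cases, with RSAD2, the antiviral enzyme viperin, at -1.65 (SE 0.87) and IFIT2 at -0.79 (SE 0.36) (adjusted p = 9.63e-03, and adjusted p = 0.976 with an estimated correlation). Genes of the growth hormone and insulin-like growth factor axis were higher in 20 of 24 cases, with STAT5A at 0.37 (SE 0.15) and AKT1 at 0.39 (SE 0.18), both signal carriers that many receptors share (adjusted p = 9.81e-04, and adjusted p = 0.775 with an estimated correlation). The lower spike-in class held 3 low arrays and 1 high array, and with the class as a block the monocyte call ended (adjusted p of 0.0847) at a mean difference of -0.49 (SE 0.26), against -0.48 (SE 0.22) without it. In the higher class (2 low, 4 high) the monocyte and interferon-stimulated means differed by -0.73 and -0.71. The interferon-stimulated call ended without low replicates 3 (0.11) and 4 (0.132) and high replicates 1 (0.356) and 4 (0.341), and the monocyte call without high replicate 4 (0.0879), at a mean of -0.318. Without the 4 arrays that ended its call the interferon-stimulated mean was -0.459, -0.377, -0.375 and -0.359 in that order, against -0.53 (SE 0.46). It was -0.814 without high replicate 3 and -0.346 without high replicate 5, the array with the lowest median correlation in the pair (0.920), where the call held.

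Genes without overlap in that pair included ATP1B1, a sodium pump subunit, at -1.31 (SE 0.26), QPCT, which forms pyroglutamate on peptides, at -1.32 (SE 0.28) and SCD, the stearoyl-CoA desaturase, at -0.90 (SE 0.20). MAT2B, TSPYL1, NPL and DR1 were lower, between -0.87 and -0.65. STK11, a kinase that activates AMPK, was higher by 0.54 (SE 0.14) and TRA2B, a splicing factor, by 0.72 (SE 0.20). ZBTB48, CC2D1A, SHARPIN, RRP1B, DCAF15 and JMJD7 were higher by 0.38 to 0.54. The adjusted p was 0.749 for all 16. IL10 measured 8.03 ± 0.74 and 8.74 ± 0.75, a difference of 0.72 (SE 0.41, p adjusted over the trait genes alone 0.303). In limma 0 probe sets passed the adjusted threshold and 1483 had an unadjusted p under 0.05, 557 higher and 926 lower. The excess of lower probe sets depended on the scaling: centred on the array median 774 were higher and 753 lower, and with renewed quantile normalization 755 and 790. With the spike-in class as a block 25 probe sets passed and 4596 had an unadjusted p under 0.05. Groups did not overlap for 268 probe sets, 1.12% against 0.794% by chance.

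In the CD8+ and IFN-alpha pair CD8A was higher in the high group, 9.45 ± 0.31 against 10.84 ± 0.60, a difference of 1.40 (SE 0.27). It passed when adjusted over the trait genes alone (0.00134) but not over all probe sets (1.0); CD8B differed by 0.73 (SE 0.34, p adjusted over the trait genes alone 0.133). Cytotoxic and NK cell genes were higher in 10 of 12 cases, with CD8A the only gene to pass over the list alone and GZMH at 0.87 (SE 0.33); the list had adjusted p = 1.21e-05 in camera, and adjusted p = 0.258 with an estimated correlation. T cell genes were higher in 11 of 11 cases, with CD3E, a chain of the T cell receptor complex, at 0.62 (SE 0.26) (adjusted p = 3.43e-05, and adjusted p = 0.282 with an estimated correlation). Receptor signalling genes were higher in 13 of 15 cases, with RASGRP1 at 0.62 (SE 0.23) (adjusted p = 3.64e-04, and adjusted p = 0.258 with an estimated correlation). Cell cycle genes were higher in 21 of 22 cases, with TYMS, thymidylate synthase, at 0.69 (SE 0.26) and CDC45, a replication helicase subunit, at 0.43 (SE 0.16) (adjusted p = 4.31e-08, and adjusted p = 0.52 with an estimated correlation). In the higher spike-in class (4 low, 4 high) the cytotoxic, T cell and cell cycle means differed by 0.37, 0.48 and 0.22, against 0.47 (SE 0.18), 0.36 (SE 0.18) and 0.35 (SE 0.23) over all arrays; the lower class held 1 array of each group. Without high replicate 5 the cell cycle mean differed by only 0.191, although the list was still called.

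Genes of oxidative phosphorylation were higher in this pair in 41 of 45 cases by a mean of 0.12 (SE 0.10) (adjusted p = 2.58e-04, and adjusted p = 0.671 with an estimated correlation), and ribosomal protein genes in 52 of 59 by a mean of 0.08 (SE 0.07) (adjusted p = 3.87e-03, and adjusted p = 0.907 with an estimated correlation). Myeloid genes were lower: S100A8, a calcium-binding protein of neutrophils, differed by -1.20 (SE 0.62) and 10 of 13 neutrophil genes were lower (adjusted p = 0.0214, and adjusted p = 0.671 with an estimated correlation). Among monocyte genes 11 of 15 were lower, with FCGR1A, an Fc receptor, at -0.40 (SE 0.18) (adjusted p = 0.024, and adjusted p = 0.671 with an estimated correlation). Platelet genes were lower in 7 of 10 cases, with PPBP at -0.75 (SE 0.46) (adjusted p = 0.0492, and adjusted p = 0.671 with an estimated correlation). Interferon-stimulated genes were lower in 19 of 23 cases, with OAS1 at -1.68 (SE 1.31), but GBP1 was higher by 0.68 (SE 0.24) (adjusted p = 0.0407, and adjusted p = 0.907 with an estimated correlation). Without low replicate 2 the calls of the neutrophil, interferon-stimulated, ribosomal, monocyte and platelet lists ended, at adjusted p of 0.499, 0.95, 0.354, 0.402 and 0.077. Without high replicate 5 the neutrophil (0.312), interferon-stimulated (0.825), monocyte (0.683), platelet (0.565) and oxidative phosphorylation (0.174) calls ended. Without low replicate 3 this held for neutrophils (0.156), interferon-stimulated genes (0.267), monocytes (0.0745) and platelets (0.173), and without low replicate 4 for interferon-stimulated genes (0.0546), monocytes (0.175), platelets (0.247) and ribosomal proteins (0.0514). Leaving out high replicate 2 ended the neutrophil (0.0547), interferon-stimulated (0.431), platelet (0.0551) and ribosomal (0.0605) calls. The platelet call also ended without low replicate 1 (0.174) and high replicate 3 (0.604), the neutrophil call without high replicate 4 (0.0619) and the interferon-stimulated call without high replicate 1 (0.052). With the actin covariate the interferon-stimulated call ended (0.201) at -0.23 (SE 0.56), against -0.27 (SE 0.46).

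The interferon-stimulated mean of this pair was -0.0454 without low replicate 2, -0.0861 without high replicate 5 and -0.122 without high replicate 2. It was -0.191 without low replicate 3, and stayed at -0.288 and -0.268 without low replicate 4 and high replicate 1. The neutrophil mean, -0.27 (SE 0.34) over all arrays, was -0.04 without low replicate 2 and -0.152 without high replicate 5. It was -0.191, -0.25 and -0.226 without low replicate 3 and high replicates 2 and 4. The monocyte mean, -0.25 (SE 0.34) over all arrays, was -0.0579, -0.2 and -0.17 without low replicates 2, 3 and 4, and -0.0624 without high replicate 5. For platelets, -0.26 (SE 0.32) over all arrays, the means without low replicates 1, 2, 3 and 4 were -0.226, -0.28, -0.22 and -0.173, and those without high replicates 2, 3 and 5 were -0.287, -0.11 and -0.0997. The ribosomal mean was 0.0321 and 0.078 without low replicates 2 and 4 and 0.0637 without high replicate 2, and the oxidative phosphorylation mean was 0.0543 without high replicate 5. Where the calls held, leaving out low replicate 1 gave -0.491 for interferon-stimulated genes, -0.406 for neutrophils, -0.386 for monocytes and 0.124 for ribosomal proteins. Leaving out low replicate 5 gave -0.428 for monocytes, -0.417 for platelets and 0.073 for oxidative phosphorylation. High replicate 3 gave -0.585 for interferon-stimulated genes and -0.453 for neutrophils when left out, and high replicates 1 and 4 gave -0.397 and -0.422 for platelets.

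Genes without overlap in that pair included LMO4, a transcriptional cofactor, at 1.30 (SE 0.31) and the calcium sensor NCALD at 0.74 (SE 0.18). MLLT11, POLR3A, VPS16 and TRIP13 were higher by 0.38 to 0.53. CALD1, an actin-binding protein, differed by -1.51 (SE 0.35), HPSE, the enzyme heparanase, by -0.97 (SE 0.28) and LIPA, the lysosomal acid lipase, by -0.74 (SE 0.17). TIMP3, CLTA and RFC1 were lower, between -0.48 and -0.33. IFNA1, IFNAR1 and IFNAR2 differed by -0.04, 0.06 and 0.18, all with p adjusted over the trait genes alone of 0.852. With limma, the adjusted threshold was passed by 0 probe sets and 474 had an unadjusted p under 0.05, 287 higher and 187 lower; these were 233 and 232 centred on the array median, 166 and 346 with the actin covariate and 223 and 281 without low replicate 5. With array weights 2551 did, and 862 in the higher spike-in class alone, where 2 passed the adjusted threshold. High and low arrays did not overlap for 68 probe sets, 0.283% against 0.794% by chance.

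In the CD8+ and IL-10 pair all 23 interferon-stimulated genes were higher in the high group. IFIT1 measured 12.06 ± 0.70 and 13.24 ± 0.35, a difference of 1.18 (SE 0.31), and MX1 11.24 ± 0.71 and 12.50 ± 0.57, a difference of 1.26 (SE 0.36). ZBP1, a sensor of nucleic acids, was higher by 1.79 (SE 0.53), RSAD2 by 2.48 (SE 0.80), and IFIT3 and XAF1 by 1.31 (SE 0.43) and 1.20 (SE 0.40); 8 of the 23 passed when adjusted over the list alone and none over all probe sets. The list mean differed by 1.09 (SE 0.40), with 3 of 5 high arrays (11.03 to 11.11) above all low arrays (9.16 to 10.68) and the other 2 (9.91 and 10.01) among them (two-sided exact permutation p = 0.0397, 0.198 adjusted over the lists, where 0.00794 is the smallest p that 5 against 5 allows). The list had adjusted p = 9.88e-24 in camera, and adjusted p = 0.21 with an estimated correlation. Monocyte genes were higher in 14 of 15 cases: CD14, the monocyte receptor for lipopolysaccharide, measured 7.46 ± 0.82 and 9.62 ± 1.21, a difference of 2.15 (SE 0.56) that passed over the list alone, and TLR4, its signalling partner, differed by 1.16 (SE 0.56) (adjusted p = 9.72e-07, and adjusted p = 0.21 with an estimated correlation). In the higher spike-in class (3 low, 4 high) the interferon-stimulated and monocyte means differed by 1.5 and 0.83, while the lower class held 2 low arrays and 1 high array. The higher EIF1AY class held 0 low and 3 high pigs, the same 3 that lay above all low arrays, and with EIF1AY as a covariate these means differed by 0.43 (SE 0.41) and 0.37 (SE 0.33), CD14 by 0.97, TLR4 by 0.64, ZBP1 by 0.75 and RSAD2 by 1.39.

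Class I antigen presentation genes were higher in this pair in 14 of 15 cases, with PSMB8, a subunit of the immunoproteasome, at 0.87 (SE 0.30) (adjusted p = 2.99e-04, and adjusted p = 0.346 with an estimated correlation). Class II genes were higher in 12 of 14 cases, with SLA-DMA at 0.58 (SE 0.32) (adjusted p = 0.0205, and adjusted p = 0.723 with an estimated correlation). Eosinophil and basophil genes were higher in 4 of 5 cases, with ALOX15, a lipoxygenase, at 1.36 (SE 0.46) (adjusted p = 0.0205, and adjusted p = 0.21 with an estimated correlation). The list for production and sensing of IFN-alpha was higher in 11 of 18 cases, with the innate adaptor MYD88 at 1.25 (SE 0.40) and IRF7, an interferon-inducing transcription factor, at 1.27 (SE 0.43) (adjusted p = 0.0473, and adjusted p = 0.21 with an estimated correlation). Inflammatory genes were higher in 15 of 19 cases, with CASP1, which matures interleukin 1, at 1.39 (SE 0.44) (adjusted p = 0.0489, and adjusted p = 0.723 with an estimated correlation). Platelet genes were higher in 8 of 10 cases, with CLU at 0.53 (SE 0.25) (adjusted p = 0.0462, and adjusted p = 0.723 with an estimated correlation). With EIF1AY as a covariate the class I, platelet, IFN-alpha and inflammatory calls ended (adjusted p of 0.0624, 0.137, 0.44 and 0.946). Their means were 0.15 (SE 0.23), 0.22 (SE 0.42), 0.10 (SE 0.08) and 0.03 (SE 0.38), against 0.29 (SE 0.17), 0.32 (SE 0.30), 0.29 (SE 0.10) and 0.36 (SE 0.30) without it. PSMB8, MYD88 and IRF7 then differed by 0.47, 0.77 and 0.42. With the spike-in class as a block the class II call ended (0.0637) at 0.21 (SE 0.33), against 0.29 (SE 0.33). Without low replicate 4, the array with the lowest median correlation in the pair (0.920), the class II (0.989), class I (0.0741) and IFN-alpha (0.0626) calls ended. Without high replicate 1 the inflammatory (0.991), IFN-alpha (0.148) and eosinophil (0.0609) calls ended, and without high replicate 2 the class II (0.188), inflammatory (0.091) and IFN-alpha (0.0961) calls. Without low replicate 1 this held for the platelet (0.578), inflammatory (0.38) and IFN-alpha (0.209) calls, and without low replicate 2 for the platelet (0.207), inflammatory (0.164) and eosinophil (0.0697) calls. Leaving out low replicate 5 ended the inflammatory (0.183) and IFN-alpha (0.0642) calls, high replicate 3 the platelet call (0.316), high replicate 4 the platelet and eosinophil calls (0.101 each) and high replicate 5 the IFN-alpha call (0.0533). With the actin covariate the eosinophil (0.0629) and platelet (0.0573) calls ended at 0.52 (SE 0.31) and 0.29 (SE 0.40), against 0.59 (SE 0.23) and 0.32 (SE 0.30).

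In the same pair, leaving out low replicate 4 gave means of -0.0154 for class II and 0.144 for class I, while the IFN-alpha mean stayed at 0.292. The IFN-alpha mean also moved by less than 1.5 times without low replicates 1 and 5 (0.253 and 0.284) and high replicates 1, 2 and 5 (0.267, 0.314 and 0.225). The inflammatory mean was 0.143 without high replicate 1, 0.413 without high replicate 2, and 0.299, 0.312 and 0.322 without low replicates 1, 2 and 5. The platelet mean was 0.122 and 0.226 without low replicates 1 and 2, and 0.163 and 0.291 without high replicates 3 and 4. The eosinophil mean was 0.458, 0.599 and 0.44 without low replicate 2 and high replicates 1 and 4, and the class II mean 0.213 without high replicate 2.

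Genes without overlap in the CD8+ and IL-10 pair included GM2A, an activator of lysosomal ganglioside breakdown, at 1.25 (SE 0.21), VDAC2, a channel of the outer mitochondrial membrane, at 1.53 (SE 0.36; 0.83 with EIF1AY as a covariate) and AP2S1, a subunit of the clathrin adaptor, at 0.79 (SE 0.18). KLHL20, AGPAT4, ANKFY1 and WDFY2 were higher by 0.54 to 0.78, and AGPAT4 by 0.41 with the same covariate. ENO3, the muscle enolase, differed by -0.76 (SE 0.20), and AMT, ZP3, KNSTRN and LOC100513863 were lower, between -0.33 and -0.17. CD8A measured 9.81 ± 1.43 and 9.88 ± 0.80, and IL10 differed by -0.60 (SE 0.45, p adjusted over the trait genes alone 0.852). At the adjusted threshold limma gave 0 probe sets and 606 had an unadjusted p under 0.05, 462 higher and 144 lower; with EIF1AY as a covariate the unadjusted count was 192, and in the higher spike-in class alone it was 3134, 1258 higher and 1876 lower. Without low replicate 4 the numbers were 694 higher and 666 lower. Groups did not overlap for 71 probe sets, 0.296% against 0.794% by chance.

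**Figure D2:**
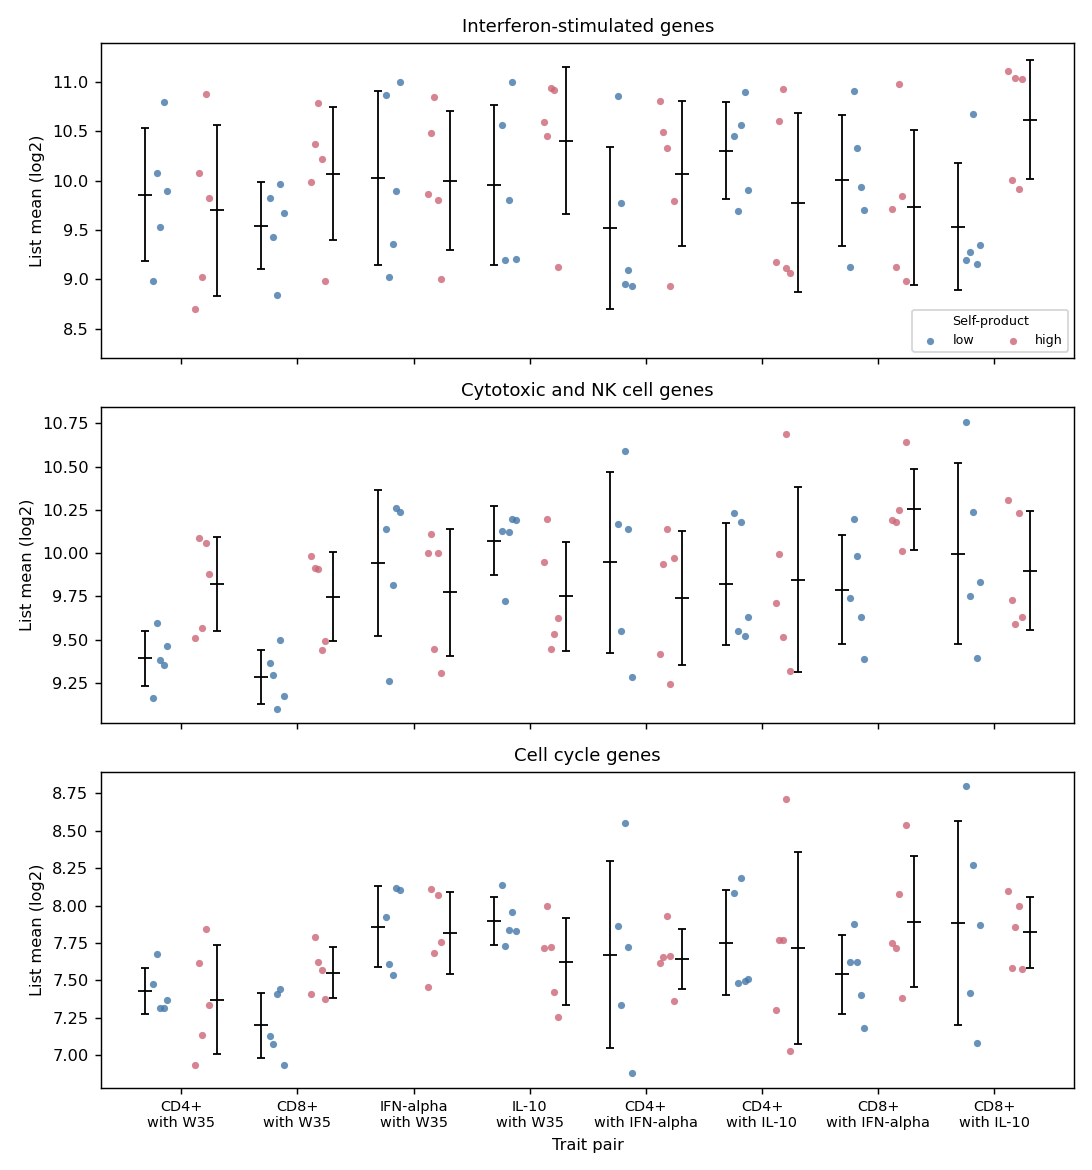
Mean log2 value (vertical) of the interferon-stimulated, cytotoxic and NK cell, and cell cycle lists on every array of the 8 trait pairs (horizontal), in the low (blue) and high (red) self-product groups, with 5 points per group; black marks are the group mean and SD. In CD8+ with IL-10, 3 of 5 high arrays lie above all low arrays for interferon-stimulated genes, and in CD4+ with W35 and CD8+ with W35 3 of 5 do for cytotoxic genes.

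Between pairs, the differences of all probe sets were correlated across genes, which are not independent replicates, and set beside 100 permutations of pigs that kept which arrays were shared. The 28 correlations ran from -0.50 to 0.68, and 2 lay outside the permutation range where 1.4 were expected. These were CD4+ and W35 against CD4+ and IFN-alpha (r = -0.50, range -0.39 to 0.26) and CD4+ and IFN-alpha against CD4+ and IL-10 (r = -0.45, range -0.42 to 0.32). The highest, CD4+ and W35 against CD4+ and IL-10 (r = 0.68), lay inside its range of -0.06 to 0.71 with the shared pigs and outside it without them (r = 0.50, range -0.38 to 0.32). CCL5 was higher in CD4+ with W35 and CD8+ with W35 and at -1.03 in IL-10 with W35. The first 2 share 5 pigs, all with the same label, so they are not independent: their correlation over all probe sets was 0.49 where the permutations averaged 0.50, and -0.06 without the shared pigs. IL-10 with W35 also shares 3 pigs with CD4+ with W35, 2 of them with opposite labels, and 3 with CD8+ with W35, all 3 with opposite labels. Its CCL5 value is therefore not independent of theirs. RRM2 was higher in CD8+ with W35 and lower in IL-10 with W35, which share those 3 pigs with opposite labels.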

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

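The tests with the spike-in class, the EIF1AY class, the actin covariate and the shares of neutrophils and erythroid cells were chosen after the results they concern had been seen, as was the bound of 2 SE for the tests that leave out 1 array.

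In no pair was chance excluded for the number of probe sets at unadjusted p under 0.05 or of lists. The splits were fitted with the group term alone. They therefore do not cover the 4596 probe sets that CD4+ with IL-10 gave with the spike-in class as a block. With adjusted p under 0.05 in limma, the real groups of all 8 pairs gave 0 probe sets, so that 100 of 100 splits give as many whatever the data, which decides nothing; the highest other counts were 63 (CD4+ with W35), 1 (CD8+ with W35), 1 (IFN-alpha with W35), 3530 (IL-10 with W35), 7 (CD4+ with IFN-alpha), 69 (CD4+ with IL-10), 1164 (CD8+ with IFN-alpha) and 269 (CD8+ with IL-10). In the same order, the real counts at unadjusted p under 0.05 were 2143, 822, 1018, 766, 929, 1483, 474 and 606. Splits with as many numbered 11, 57, 53, 54, 42, 22, 79 and 59 of 100, and the highest other counts were 3925, 4123, 3897, 8047, 6947, 4856, 7238 and 6374. For called lists the real counts were 1, 11, 1, 5, 5, 3, 10 and 8. There, 93, 14, 99, 65, 88, 96, 25 and 55 of 100 splits gave as many, with highest other counts of 17, 19, 13, 12, 13, 13, 16 and 12. Some splits called several times the real count. These are the highest of many splits, and whether a structure of the samples lies behind them was not tested.

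Interferon-stimulated genes were higher by 1.09 in the CD8+ and IL-10 pair. With the spike-in class as a block the difference was 1.10 (SE 0.43). Within the higher spike-in class all high arrays (9.91 to 11.11) lay above all low arrays (9.20 to 9.35). This argues against the class as the whole cause. In the lower spike-in class the 1 high array (10.01) lay between the 2 low arrays (9.155 and 10.68), too few to show whether the difference holds there. The tables also argue against 1 array, since the smallest difference without any 1 array was 0.964 (SE 0.43). The EIF1AY class of the pigs stays open: with EIF1AY as a covariate the difference was 0.433 (SE 0.41), within 2 SE of 0, and the 3 pigs of the higher class are the 3 high arrays above all low arrays. The self-product itself also stays open.

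Cytotoxic and NK cell genes were higher by 0.429 in CD4+ with W35 and by 0.463 in CD8+ with W35. With the spike-in class as a block the differences were 0.432 (SE 0.15) and 0.473 (SE 0.15), and the smallest without 1 array were 0.362 (SE 0.14) and 0.404 (SE 0.14), which argues against both as the whole cause; within the higher class alone they were 0.28 and 0.18. Without the pigs that the pairs share they were 0.393 (SE 0.16) and 0.479 (SE 0.20), near the values over all arrays. With only 2 low and 3 high arrays left in each pair, this is too few to exclude that the shared arrays account for the likeness. A lower share of neutrophils would need a lower neutrophil list mean. That mean differed by 0.0377 (SE 0.29) and 0.34 (SE 0.28), on the other side but within its error, so a lower share stays open. The erythroid list mean was lower in the high group of both pairs. It was 8.76 ± 0.72 against 8.10 ± 0.51 in CD4+ with W35, and differed by -0.425 (SE 0.37) in CD8+ with W35. A lower share of erythroid cells was not tested for the cytotoxic genes and stays open too. The biological explanation, the self-product, stays open beside these.

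Cell cycle genes were higher by 0.354 in CD8+ with W35 and lower by -0.275 (SE 0.15) in IL-10 with W35, the latter within 2 SE of 0 with all arrays. RRM2 at 1.42 and -1.08, and APITD1 at 0.733 and -0.821, stood apart between the pairs because every high array lay above every low array in the first and below in the second; the difference between pairs was not tested. In the first pair the spike-in class (0.347, SE 0.135, as a block) and 1 array (0.288, SE 0.12) are argued against; in the second 1 array (-0.182, SE 0.13) and the class, which there is 1 array (-0.214, SE 0.15), stay open, since the plain difference is itself too imprecise for these tests to decide. Without the 3 shared pigs, all with opposite labels, the differences were 0.291 (SE 0.17; 5 low, 2 high) and -0.208 (SE 0.22; 2 low, 5 high), too imprecise to exclude that the shared pigs account for the opposite signs. The erythroid list differed by -0.425 (SE 0.37) and 0.284 (SE 0.38), opposite in sign to the cell cycle genes but within its error. The share of erythroid cells therefore stays open too, as does the self-product.

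Single arrays lay far from the other 4 of their group in 36 of 648 gene and group combinations (5.56%), where chance gives about 1 in 20; 7 of these were on 1 pig. In CD4+ with W35 these were ZC3H11A in the low group (8.05, others from 8.72) and, in the high group, MAP4K4 (6.78, others to 6.03) and KLK7 (7.82, others to 7.09). In CD8+ with W35, all in the low group, they were CD8A (7.86), CCL4 (9.24), TNF (10.4) and RPL8 (13.4). In IFN-alpha with W35 high it was GNG11 (12.7). In IL-10 with W35 they were SPPL3 (8.76), IGF2 (8.64) and MX1 (10.8) in the high group and IGF1 (6.59) in the low group. In CD4+ with IFN-alpha they were ITGA2B (11.3), IFIT2 (10.4) and MAN1C1 (7.02) in the high group, all on replicate 1, and ALDH3A2 (6.82) and CLU (10.1) in the low group. In CD4+ with IL-10 low they were ZBTB48 (6.71), TSPYL1 (10.3) and AKT1 (10.7). In CD8+ with IFN-alpha they were CDC45 (7.52), TIMP3 (5.27), AIF1 (10), PCNA (11.2) and COX7C (11.9) in the high group, and RFC1 (7.75), IFI35 (11.1) and TYMS (6.87) in the low group. In CD8+ with IL-10 they were ZP3 (6.29), KNSTRN (7.23), GNG11 (10.9), ZBP1 (9.63) and SLA-DMA (9.08) in the low group, and ZP3 (5.44), VCAN (7.72) and CLU (12.1) in the high group.

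The 28S rRNA control, outside the compared probe sets, lay far from the other 4 arrays in 3 of 16 groups: 9.12 in high replicate 4 of CD8+ with W35 (others 13.8 to 14.3), 13.6 in high replicate 3 of CD4+ with IFN-alpha (others from 14.0) and 13.6 in low replicate 1 of CD4+ with IL-10. The first of these is the array without which the called lists of CD8+ with W35 numbered 6, against 11, and the T cell, erythroid, class II, ribosomal, neutrophil and inflammatory calls ended. With the actin difference as a covariate, an RNA quality setting chosen after seeing the data, the class II and inflammatory calls ended (adjusted p of 0.0722 each), while the T cell (0.00221), erythroid and neutrophil (0.0259 each) and ribosomal (1.89e-05) lists were called. The 28S rRNA value itself was not used as a covariate.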

How the results depend on the processing

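The spike-in, EIF1AY and actin settings and the exact permutation test were chosen after seeing the data; the rest were fixed before. In limma, 0 probe sets at adjusted p under 0.05 stood in all 8 pairs under renewed quantile normalization, centring, the median filter, trend and robust moderation, an adjusted p under 0.1, 1 probe set per gene and the actin covariate. With the replicate block it was also 0, and the unadjusted counts were 2737, 878, 1152, 834, 728, 1421, 586 and 650. All lists of 8 values are in the order CD4+ with W35, CD8+ with W35, IFN-alpha with W35, IL-10 with W35, CD4+ with IFN-alpha, CD4+ with IL-10, CD8+ with IFN-alpha and CD8+ with IL-10. The adjusted count was 4 in CD4+ with IFN-alpha with blood covariates and 4 with EIF1AY, 25 in CD4+ with IL-10 with the spike-in block, 2 in CD8+ with IFN-alpha in the higher spike-in class alone and 1 in IL-10 with W35 with array weights. Leaving out 1 array gave 0 to 6 in CD4+ with W35 (6 without low replicate 2, 2 without high replicate 4), 0 to 1 in IFN-alpha with W35 (low replicate 3), 0 to 2 in IL-10 with W35 (high replicate 5) and 0 to 7 in CD4+ with IFN-alpha (low replicate 1), and 0 in the other 4 pairs. Without that low replicate 1 the groups of CD4+ with IFN-alpha coincide with the EIF1AY classes. High replicate 5 of IL-10 with W35 is the only high array of the lower EIF1AY class in its pair.

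Unadjusted counts were 1263, 481, 514, 407, 456, 728, 239 and 322 with the median filter, and 563, 253, 298, 253, 230, 371, 119 and 174 with 1 probe set per gene, both of which test fewer probe sets. At p under 0.01 and at least 1.5-fold they were 313, 104, 98, 114, 91, 190, 55 and 66, a stricter threshold. For the other settings the cause was not tested. Array weights gave 1635 in CD8+ with W35, 2037 in IL-10 with W35, 2012 in CD4+ with IFN-alpha, 2551 in CD8+ with IFN-alpha and 1129 in CD8+ with IL-10. Blood covariates gave 944 in CD4+ with W35 and 1747 in CD4+ with IFN-alpha. The spike-in block gave 1562 in IFN-alpha with W35 and 4596 in CD4+ with IL-10, and the higher class alone 2279 in CD4+ with IL-10, 862 in CD8+ with IFN-alpha and 3134 in CD8+ with IL-10. EIF1AY gave 192 in CD8+ with IL-10. Leaving out 1 array gave 1118 to 2744, 606 to 1946, 743 to 1750, 440 to 1247, 480 to 1684, 910 to 2704, 278 to 1190 and 337 to 1360. The arrays that moved the count by over 1.5 times were, in CD4+ with W35, low replicates 4 (1118) and 5 (1195); in CD8+ with W35, high replicate 5 (1946); in IFN-alpha with W35, low replicates 1 (1671) and 3 (1750); and in IL-10 with W35, high replicates 4 (440) and 5 (1247). In CD4+ with IFN-alpha they were low replicate 2 (1684) and high replicates 1 (480) and 3 (577), and in CD4+ with IL-10 low replicates 1 (924) and 4 (910) and high replicate 1 (2704). In CD8+ with IFN-alpha they were low replicates 1 (1190) and 4 (756) and high replicates 1 (313), 3 (902) and 5 (278), and in CD8+ with IL-10 low replicate 4 (1360) and high replicates 1 (922), 3 (387) and 5 (337).

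The exact permutation test had 1, 3, 0, 0, 0, 1, 2 and 5 lists at an unadjusted exact p under 0.05. Its smallest possible p was 0.00794. Several lists of a pair would therefore have to separate completely or nearly so before any passed after adjustment, and its count of 0 decides little. Called lists numbered 0 in every pair with an estimated correlation, with fry and with that test. They numbered 3, 5 and 9 in CD4+ with W35, IFN-alpha with W35 and CD4+ with IFN-alpha in the higher spike-in class alone. With EIF1AY they numbered 2 in IFN-alpha with W35, 11 in IL-10 with W35 and 12 in CD4+ with IFN-alpha. Array weights gave 3 in IFN-alpha with W35 and 3 in IL-10 with W35, the mean of a gene's probe sets 3 in IFN-alpha with W35 and 5 in CD8+ with IL-10, and the replicate block and the actin covariate 2 each in IFN-alpha with W35. Leaving out 1 array gave 1 to 4, 6 to 13, 0 to 6, 3 to 9, 2 to 9, 2 to 5, 5 to 12 and 5 to 11. The number moved by over 1.5 times in CD4+ with W35 without low replicates 1 (2) and 3 (3) and high replicates 1 (2), 2 (2), 3 (3) and 4 (4), and in CD8+ with W35 without low replicate 1 (7) and high replicate 4 (6). In IFN-alpha with W35 it moved without low replicates 1 (4), 2 (6), 3 (2), 4 (6) and 5 (0) and high replicates 1 (2), 2 (2), 3 (2) and 5 (5), and in IL-10 with W35 without low replicate 5 (3) and high replicates 2 (9) and 3 (3). In CD4+ with IFN-alpha it moved without low replicate 5 (9) and high replicates 2 (2) and 3 (8), in CD4+ with IL-10 without high replicate 2 (5), in CD8+ with IFN-alpha without low replicates 3 (6) and 4 (6) and high replicates 2 (6) and 5 (5), and in CD8+ with IL-10 without high replicate 2 (5). Each call was checked under 22 settings, 10 of them leaving out 1 array. The cytotoxic calls in CD4+ with W35 and CD8+ with W35 held in 18, and the cell cycle calls and the interferon-stimulated call in CD8+ with IL-10 in 19, each including all 10 that leave out 1 array. A call could hold while the mean moved: the cell cycle mean was 0.191 in CD8+ with IFN-alpha and -0.182 in IL-10 with W35 without high replicate 5 of each, against 0.353 and -0.275. Other calls held in fewer: in IL-10 with W35 T cells in 7 and cytotoxic genes in 9, in CD8+ with IL-10 IFN-alpha production in 8 and platelets and inflammatory genes in 10, in CD8+ with IFN-alpha platelets in 10 and interferon-stimulated genes in 11, and in CD8+ with W35 inflammatory genes in 11. The other calls held in 13 to 19.

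Of the trait genes, 2 passed when adjusted over the trait genes alone, IL10 in IL-10 with W35 and CD8A in CD8+ with IFN-alpha. The number was 4 with blood covariates (also IFNAR1 and IFNAR2 in IFN-alpha with W35), and 1 with quantile normalization, the spike-in block or EIF1AY, where CD8A was left. Leaving out the same replicate of 1 group in every pair gave 1 to 2, and IL10 was lost without low replicates 1, 3, 4 or 5 or high replicates 3 or 4; without the last, CD8B passed beside CD8A. Another probe set of IFNAR2 in IFN-alpha with W35 gave a log2 difference of 0.0167 in place of -0.42. The agreement of pairs lay outside its permutation range in 1 of 28 with the median filter, against 2, and in 3 of 22 without shared pigs. A signal over background was not tested, since the values give no background.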

Other observations

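The comparison of EIF1AY classes over pigs, the genes of untested lists and the measures of splits were chosen after the results had been seen.

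Over the 29 pigs, taken once each after a common quantile normalization, interferon-stimulated genes were among the most variable lists: the list mean ran from 8.96 to 11.01 (SD 0.63). The erythroid list ran from 7.52 to 9.77 (SD 0.61) and the neutrophil list from 8.2 to 10.33 (SD 0.48). Inflammatory cytokine genes ran from 7.69 to 9.29 (SD 0.49). Ribosomal protein genes and genes of lipid and cholesterol metabolism varied least among these examples, with SD 0.14 and 0.12. RSAD2, an antiviral enzyme, measured 9.87 ± 1.19 in the 11 pigs of the higher EIF1AY class and 9.06 ± 1.57 in the 18 of the lower, and USP18, which removes the ubiquitin-like ISG15, 9.89 ± 0.92 and 9.28 ± 0.59.

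A hypothesis was that interferon-stimulated genes differ between the EIF1AY classes of pigs, which may differ in sex. The list mean was 10.13 ± 0.64 in the higher and 9.72 ± 0.58 in the lower class, a difference of 0.411 (SE 0.24; permutation p = 0.086, 0.572 adjusted over 25 lists), with 22 of 23 genes higher. Within the lower spike-in class it was -0.54 (4 pigs against 7) and within the higher class 0.98 (7 against 11), so the relation did not hold within both classes. The test cannot tell whether the classes differ, and the bounds that it was judged by were set after its value was seen.

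Lists with fewer than 5 genes on the array were not tested: those for B cells, plasma cells and dendritic cells had 4 genes each, that for sex-linked genes 2 and that for gamma delta T cells 0. BTK, a kinase of B cells and myeloid cells, differed by -0.90 (SE 0.42) in CD4+ with W35, -0.73 (SE 0.22) in CD4+ with IL-10 and 0.53 (SE 0.26) in CD8+ with IL-10, and by -0.03 to 0.19 in the other 5 pairs. TCF4, a transcription factor of plasmacytoid dendritic cells, was higher by 0.65 (SE 0.22) in CD4+ with W35, 0.61 (SE 0.25) in CD8+ with W35 and 0.55 (SE 0.18) in IFN-alpha with W35, but differed by -0.40 (SE 0.26) in IL-10 with W35 and -0.56 (SE 0.29) in CD8+ with IL-10. In CD4+ with IL-10, CD8+ with IFN-alpha and CD4+ with IFN-alpha it differed by 0.53, 0.49 and -0.17. These genes were chosen after their values were seen and none passed over all probe sets. The lists for CD4 helper and regulatory T cells, the glucocorticoid response, glycolysis, IL-10 signalling, lipid and cholesterol metabolism and the proteasome were called in 0 of 8 pairs.

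The splits with the highest unadjusted counts most often parted arrays by the spread of values over probe sets. The measures given were picked as the most different on the most extreme split, so they describe these splits and test no structure. In IL-10 with W35 the split with 8047 probe sets separated arrays whose SD over probe sets differed by 0.111. This was 2.81 times the pooled SD of that measure within the 2 sides, with 2 of the 5 high arrays on the first side. In CD4+ with IFN-alpha the split with 6947 separated arrays that differed in this measure by 0.122, or 2.73 times its pooled SD within the 2 sides. In CD8+ with W35 the split with 4123 followed EIF1AY, with a difference of 3.43 on the log2 scale.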
